A study of Mus musculus with 6 samples.

How the data were processed

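Total RNA of mouse cerebellum was labelled and hybridised to the Affymetrix mouse exon array (Mo_Exon ST 1.0), with 3 control arrays (Dnmt3a flx/flx) and 3 conditional knockout arrays (the same alleles with Nes-cre), per the labels. Each array was treated as a separate animal, although the labels say only that RNA came from animals of both genotypes and nothing more about how replicates were taken, so the p-values measure the spread between these samples. The extraction protocol in the labels describes a Mecp2 mutant line and another age range than the genotype and age labels do. The genotype labels and titles were used, and the value of Dnmt3a was checked in each array. Control mice carried no cre, so an effect of cre and an effect of losing Dnmt3a cannot be told apart. The labels give no hybridisation date, scan date or litter.

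The deposited table holds 1 value per gene-level probe set and array, on what its range (4.52 to 13.74) shows to be a log2 scale as deposited by the authors. The log base, the summary method, the normalization and the background correction are not given in the sources used here. Array medians lay between 8.34 and 8.36 and standard deviations between 1.82 and 1.90, so the values had been brought to a common centre but not to identical distributions. Some rows held exactly equal values in several arrays (332 rows within the 3 control arrays, 447 within the 3 cKO arrays and 33 over all 6, and between 378 and 2697 rows for any pair of arrays). The step that produced them is not known, and the spread of these rows between arrays may be understated. The submitters' processing notes name the genome build mm9, with no role. No detection call or background level was used here, and the number of arrays limits the precision.

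Probes were named through the platform's gene table, and symbols were updated through Entrez identifiers with the gene table of assembly GRCm38.p6, which was used for names only. Of 17831 rows, 15620 had 1 gene symbol, 1370 had several and 841 had none; 15559 rows were matched by identifier, and 15224 different genes were named. Rows with several symbols or none stayed in the tests and were not named. A gene with several rows was represented by the row with the highest mean over all 6 arrays. Because the assembly differs from the named build, its coordinates and gene lengths were not used, and the planned correlation of fold change with gene length was replaced by the list of very long genes that had been fixed by hand.

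The tests, gene lists, alternatives and naming rule were fixed before the data were examined, apart from the additions named in the closing parts. The deposited values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term), with Benjamini-Hochberg adjustment over all rows and an adjusted p threshold of 0.05. Of 38 gene lists, 37 with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The list of genes of X inactivation and the Y chromosome had 2 measured members and was not tested. For each list the mean difference of its members minus that of all other rows is given, together with the limma p of each member adjusted over the list alone. The same mean per array, on values centred per row, was compared between genotypes with a two-sided exact permutation test, for which 3 against 3 arrays allow no p below 0.1.

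Genes were named by rule. The rule took Dnmt3a and the DNA methylation genes with the smallest p; the 12 higher and 12 lower genes past the threshold or, with fewer, in order of p among those whose groups did not overlap; the 4 leading members of each list that passed, and 2 of the others; and 5 very long genes in each direction, for which the rule asked for genes above a length that the hand-fixed list stood in for. Nr4a1, Sema3a and the genes that describe single arrays (Ttr, Eif2s3y, Fkbp5 and others) were chosen after their values were seen.

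The steps were tested on simulated data with the rows' means and variances and 200 of 17831 rows changed, in 20 simulations of cKO against control. The gene test called 71.4% of rows changed by a log2 of 0.5 and 93.2% of rows changed by 1, and 5.53% of its calls were unchanged rows. At an unadjusted p under 0.05, with a list of each kind per simulation, camera called 100% of lists of 40 rows shifted by 0.1 and 5% of unshifted lists. Rows were simulated as independent. The list calls on the real data used the p adjusted over the lists, a stricter rule. All simulated arrays had the same noise, whereas the real arrays were unequal, so these rates are not the power of the tests here. In the real data 62 rows without overlap between the groups differed by more than 0.5, and 1 row passed.

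Alternatives were quantile normalization, centring each array on its median, the replicate number as a block, leaving out each array, leaving out the 5943 rows of lowest mean value, an intensity trend with robust variance, a test of each row without moderation, array quality weights, an adjusted p threshold of 0.1, and a fold change above 1.2. A term for the arrays with Y-linked signal, leaving out the 2 arrays low in choroid plexus transcripts, leaving out members shared by 2 lists, and 4 of the gene test settings for the Dnmt3a row were added after seeing the data. Figures were drawn with matplotlib.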

Results

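Gene expression was measured in the cerebellum of adult mice on 6 exon arrays, each hybridised with total RNA of 1 sample. The 2 groups of 3 arrays differed in genotype. Control mice carried floxed alleles of Dnmt3a, the gene of a DNA methyltransferase that sets new methyl marks on cytosine, and no cre. The conditional knockout (cKO) mice carried the same alleles with a Nes-cre transgene, in which the nestin regulatory sequence drives cre recombinase in neural precursors and hence in most neurons and glia that descend from them. The value table held 17831 rows on a log2 scale, of which 15620 could be assigned to a single gene. Values ran from 4.52 to 13.74 and array medians from 8.34 to 8.36. Pearson correlations between arrays, taken across rows, lay between 0.991 and 0.998, and cKO replicate 3 stood apart, with a highest correlation of 0.994 to any other array. All differences below are cKO minus control on the log2 scale, with the mean ± SD of n = 3 arrays per group and the standard error (SE) of the limma fit.

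Dnmt3a was examined first, as a check of the labels. Its value was 9.46 ± 0.07 in control and 8.86 ± 0.14 in cKO cerebellum (n = 3 each), a difference of -0.60 (SE 0.08), or 1.52-fold lower, and every cKO array lay below every control array. The row (probe 6792945) is a gene-level value, and how much of it comes from the floxed part is not given in the sources used here, so it is no measure of intact transcript. The limma test gave an adjusted p of 0.233 over all rows, and the adjusted p ranged from 0.0257 to 0.904 over the alternatives, the former with array quality weights, the only setting in which Dnmt3a passed. Among the 19 measured genes of the DNA methylation and methyl-CpG machinery, Dnmt3a was the only member to pass when adjusted over the list alone (adjusted p = 0.0059, limma), and no member passed over all rows. Gadd45b, a stress-inducible gene linked to DNA demethylation, had a value higher by 0.31 (SE 0.12), and Mbd2, a methyl-CpG binding protein, by 0.10 (SE 0.06). Both were highest in cKO replicate 3. Gadd45b was 9.30 there against 8.87 and 8.90 in cKO replicates 1 and 2, and Mbd2 10.44 against 10.28 and 10.27. Gadd45b is also a member of the immediate early list described below. The list as a whole did not pass the camera test (mean relative to all other rows -0.0211, adjusted p = 0.805).

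The comparison of the 2 genotypes over all genes asks which transcripts differ between Dnmt3a-floxed mice with and without Nes-cre. The highest-ranked named genes with values higher in cKO included transcription factors, a glial filament and receptors. Pbx3, a homeodomain partner of Hox proteins, was higher by 0.76 (SE 0.06), Satb1, a chromatin organiser that binds AT-rich DNA, by 0.38 (SE 0.04), and Fos, a subunit of the AP-1 factor, by 1.11 (SE 0.14). Gfap, the intermediate filament of astrocytes, was higher by 0.47 (SE 0.05). Chrna4, a nicotinic acetylcholine receptor subunit, was higher by 0.70 (SE 0.08), and Npr1, a natriuretic peptide receptor, by 0.50 (SE 0.06). The other 6 were Mab21l2 (0.62), Il15 (0.54), Nhsl1 (0.40), Cdc20 (0.38), Ppp1r1a (0.37) and Mcam (0.36). Values lower in cKO were led by Necab3, a calcium-binding protein, with a difference of -0.97 (SE 0.09), and the adaptor protein gene Stap2, with -0.98 (SE 0.12). Grk5, a kinase of G protein-coupled receptors, differed by -0.70 (SE 0.08), and Bcor, a co-repressor of BCL6, by -0.61 (SE 0.07). Dio2, the deiodinase that makes active thyroid hormone in the brain, differed by -0.40 (SE 0.05), and Plin2, a lipid droplet coat protein, by -0.51 (SE 0.07). Ephx1 (-0.39), Far2 (-0.39), Chil5 (-0.53), Endod1 (-0.29) and Map10 (-0.30) completed, with Dnmt3a, the 12 genes with lower values, which were taken in order of p.

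None of these named genes passed the limma test over all rows. The adjusted p lay between 0.218 and 0.233 for the 12 higher genes and between 0.218 and 0.272 for the 12 lower ones. For each of them the 3 cKO arrays lay on one side of the 3 control arrays, which the naming rule required. A single row passed. It has no gene name in the tables used here (probe 6756473), and its value was 7.27 ± 0.04 in control and 8.42 ± 0.07 in cKO (n = 3 each), higher by 1.15 (SE 0.05, adjusted p = 0.0106, limma). At an unadjusted limma p under 0.001 there were 56 rows, 40 higher and 16 lower, where 17.8 are expected by chance. At an unadjusted p under 0.05 there were 900 rows, 466 higher and 434 lower, where 891.6 are expected. The groups did not overlap in 1942 rows (10.9%), where chance gives 10%, and 62 of the rows without overlap differed by more than 0.5, 45 higher and 17 lower. The single call was lost with the replicate numbers as a block, with a test of each row without moderation, with a term for sex, and without any 1 array other than cKO replicate 3, while weights for array quality raised the number of calls to 57.

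**Figure D1:**
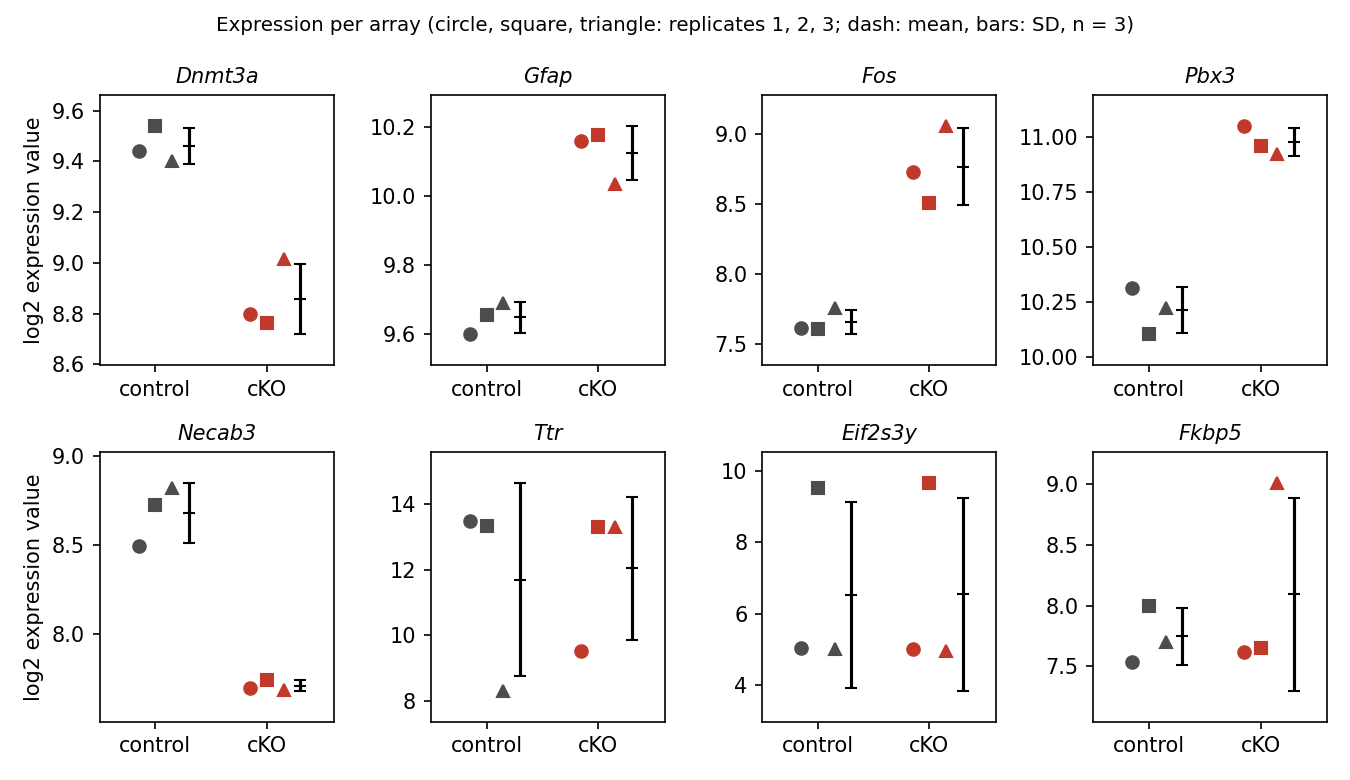
Log2 expression value (vertical axis) of 8 genes in each of the 3 control (grey) and 3 cKO (red) arrays, with circle, square and triangle for replicates 1, 2 and 3 and the group mean ± SD beside them. Dnmt3a and Necab3 are lower and Gfap, Fos and Pbx3 higher in all cKO arrays, whereas Ttr, Eif2s3y and Fkbp5 differ between arrays within a group.

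The series title names length-dependent misregulation, so very long genes were compared with other genes. The 95 measured members of a list of very long genes, which include neuronal adhesion molecules, receptors and channels, were higher in cKO than all other rows by 0.0459 on average (median difference 0.0185, 54 of 95 above 0). Nlgn1, a postsynaptic adhesion protein, rose by 0.20 (SE 0.03) and Dcc, a netrin receptor, by 0.72 (SE 0.11) when adjusted over the list alone, and no member passed over all rows. Sorcs1 (0.38), Unc5c (0.18) and Cacna2d1 (0.27) were the next members with higher values. Very long genes with lower values were led by Nrg1 (-0.24), Csmd1 (-0.18), Diaph2 (-0.32), Pard3 (-0.18) and Dlg2 (-0.15), none of which passed. At an unadjusted limma p under 0.05 there were 17 higher and 5 lower members. Lists chosen by hand as short genes were set beside the very long genes, and their gene lengths were not checked. Their median differences were 0.088 for cytosolic ribosomal protein genes (n = 43 genes), 0.0237 for respiratory chain genes (n = 63 genes) and 0.00123 for histone genes (n = 17 genes).

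By camera the very long genes passed (adjusted p = 0.00303), and over the alternatives the adjusted p ranged from 2.9e-05 to 0.711, the latter with an estimated correlation. Per array, the mean of the very long genes minus that of all other rows was -0.023 ± 0.0546 in control and 0.023 ± 0.0368 in cKO (n = 3 each, exact permutation p = 0.4, two-sided, smallest possible 0.1). Against the 3 short-gene lists together, the index of the very long genes differed by -0.0089 between cKO and control (exact permutation p = 0.7, two-sided). The difference from all other rows was 0.0154 without control replicate 2 (adjusted p = 0.409) and 0.0281 without cKO replicate 3, 0.031 without the 5943 dimmest rows (adjusted p = 0.0506), and 0.0269 (adjusted p = 0.0818) without the 10 members shared with the axon guidance list. Fold change was not related to annotated gene length itself, because no annotation of the build named for these arrays was used here.

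**Figure D2:**
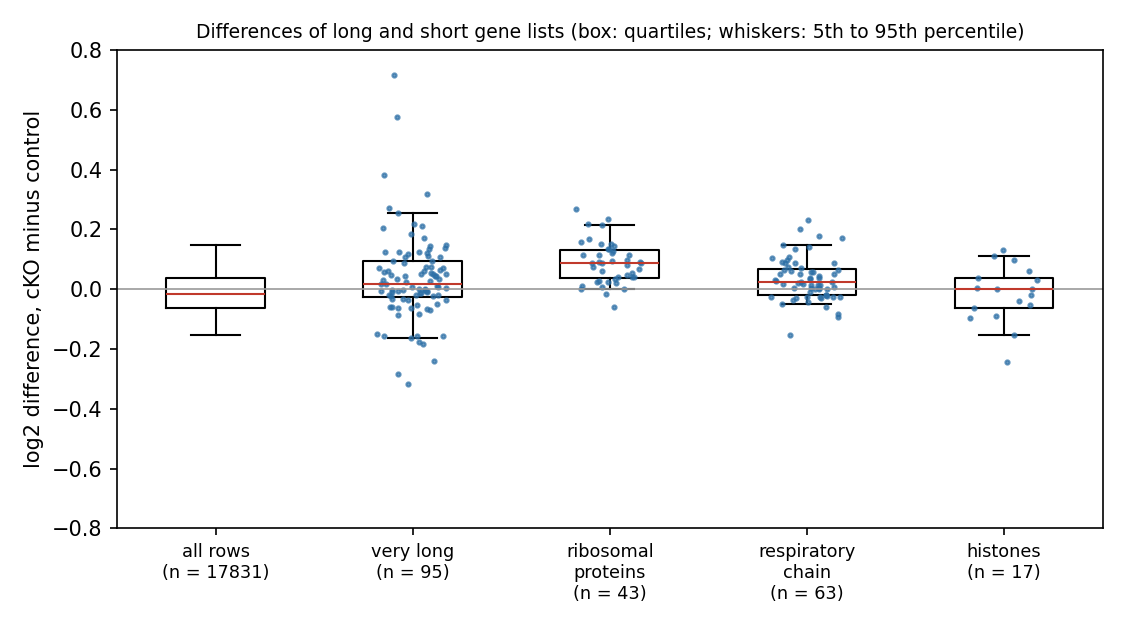
Log2 difference, cKO minus control (vertical axis), of all rows and of the members (blue points) of 1 list of very long and 3 lists of short genes. Boxes show quartiles with the median in red and whiskers the 5th to 95th percentile; the medians are -0.0147 for all rows, 0.0185 for very long genes and 0.088 for ribosomal protein genes.

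Immediate early genes, which neurons transcribe within minutes of stimulation, were the list with the largest mean difference. Their 28 measured members were higher in cKO by 0.243 relative to all other rows (19 above 0, camera adjusted p = 1.57e-05, adjusted p = 0.191 with an estimated correlation, range over the camera alternatives 3.17e-06 to 0.191). Each cKO array lay above each control array in the list's mean (exact permutation p = 0.1, the smallest possible). The groups were apart in this way, in either direction, in 8 of the 37 lists, where a share of 0.1 is expected by chance. Of these, 4 passed camera, the immediate early, astrocyte, axon guidance and imprinted lists. The lists of genes earlier studied as MeCP2 targets, antigen presentation, cell cycle and meninges were apart without passing. When adjusted over the list alone, 5 immediate early genes rose and none fell: Npas4 by 1.32 (SE 0.25), Fos by 1.11 (SE 0.14), Dusp1 by 0.79 (SE 0.11), Nr4a1 by 0.76 and Ier5 by 0.26 (SE 0.05). No member passed over all rows.

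Markers of astrocytes and Bergmann glia were higher in cKO by 0.12 relative to all other rows, with 18 of 22 measured members above 0 (camera adjusted p = 3.83e-06, adjusted p = 0.172 with an estimated correlation, range over the camera alternatives 2.2e-06 to 0.172). Gfap rose by 0.47 when adjusted over the list alone. Gja1, a gap junction protein of astrocytes, was higher by 0.26 (SE 0.07), Hopx, a marker of Bergmann glia, by 0.40 (SE 0.11), and Aldh1l1, a folate enzyme of astrocytes, by 0.14 (SE 0.05), none of which passed. The list's mean was higher in each cKO array than in each control array (control -0.06 ± 0.0264, cKO 0.06 ± 0.00527, n = 3 each, exact permutation p = 0.1). The member Fabp7 differed by -0.0026 and was highest in cKO replicate 2 and lowest in cKO replicate 3. The lists of microglia (0.0193, adjusted p = 0.317), endothelium and pericytes (-0.0153, adjusted p = 0.395) and oligodendrocytes (-0.0197, adjusted p = 0.766) did not pass. With arrays left out in turn, the microglial mean lay between 0.00686 and 0.0369 and the vascular mean between -0.0477 (without control replicate 2) and 0.00768 (without control replicate 3). The oligodendrocyte mean was 0.0769 and 0.0734 in cKO replicates 1 and 2, -0.18 in cKO replicate 3 and between -0.0335 and 0.0349 in controls, and without cKO replicate 3 the list was higher in cKO by 0.0653 and passed camera.

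Axon guidance and synaptic adhesion genes were higher by 0.0622 over 65 members, of which 41 lay above 0 (camera adjusted p = 0.00303, adjusted p = 0.227 with an estimated correlation, range over the camera alternatives 0.000554 to 0.227). Adjusted over the list alone, Nlgn1, Dcc and Efnb2, an ephrin (0.41, SE 0.08), rose and Sema3a, a repulsive guidance cue, fell by 0.40, while Epha4, an ephrin receptor, was higher by 0.26 (SE 0.06) without passing. The call was lost without control replicate 2 (0.0431, adjusted p = 0.0739) and without the members shared with the very long genes (0.0359, adjusted p = 0.162). Imprinted genes, whose expression from 1 parental allele depends on DNA methylation, were higher by 0.0593 over 39 members (21 above 0, camera adjusted p = 0.0146, adjusted p = 0.315 with an estimated correlation, range over the camera alternatives 0.0129 to 0.315). Plagl1, a zinc finger factor, was higher by 0.25 (SE 0.05), the non-coding RNA H19 by 0.30 (SE 0.07), the adaptor Grb10 by 0.18 (SE 0.04) and Gab1 by 0.12 (SE 0.04), and no imprinted gene passed when adjusted over the list alone or over all rows. The imprinted list's call was lost without control replicate 1 (0.0531, adjusted p = 0.0518).

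Ribosomal protein genes were higher by 0.0975 over 43 members, 40 of them above 0 (camera adjusted p = 7.94e-09, adjusted p = 0.711 with an estimated correlation, range over the camera alternatives 3.5e-11 to 0.711), with none past the test when adjusted over the list alone. Rpl10a (0.22, SE 0.08), Rpl35 (0.15, SE 0.04), Rplp1 (0.14, SE 0.04) and Rpl15 (0.13, SE 0.05) led the list. The list's mean was 0.177 in cKO replicate 3 and between -0.0746 and -0.00434 in the other 5 arrays, and without cKO replicate 3 the difference was 0.0336 (adjusted p = 0.0066). Core circadian clock genes were also highest in that array (0.138, against -0.0561 to 0.019 in the others). Their mean was higher by 0.0833 over 16 members, 13 above 0 (camera adjusted p = 0.0146, adjusted p = 0.371 with an estimated correlation, range over the camera alternatives 0.00632 to 0.371). Nr1d2 (0.09), Per3 (0.17), Arntl (0.23) and Clock (0.11) led the list. No clock gene had an unadjusted limma p under 0.05, and the groups overlapped for Per3 and Clock. The clock call was lost without cKO replicate 3 (0.0351, adjusted p = 0.212), without control replicate 1 (0.0824, adjusted p = 0.0518) or without control replicate 2 (0.0761, adjusted p = 0.0607), after quantile normalization (0.0679, adjusted p = 0.0602), and without the 5943 dimmest rows (0.0725, adjusted p = 0.0688). Respiratory chain genes were higher by 0.0423 over 63 members, 45 above 0 (camera adjusted p = 0.00303, adjusted p = 0.684 with an estimated correlation, range over the camera alternatives 3.32e-05 to 0.684). Cox7a2 (0.15) and Sdhb (0.23) came first, and no member had an unadjusted limma p under 0.05. Cox7a2 was 10.95 in control replicate 2 against 11.14 and 11.15 in the other controls. Sdhb was 10.69 in cKO replicate 3 against 10.40 in both other cKO arrays. The difference of the respiratory chain list was 0.00619 without control replicate 2 (adjusted p = 0.402) and 0.0227 after quantile normalization (adjusted p = 0.11). The two-sided exact permutation p was 0.2 for the ribosomal, 0.2 for the clock and 0.4 for the respiratory chain list. In the same cKO replicate 3, glucocorticoid-responsive genes had a mean of 0.545, against -0.213 to 0.0356 in the other 5 arrays.

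**Figure D3:**
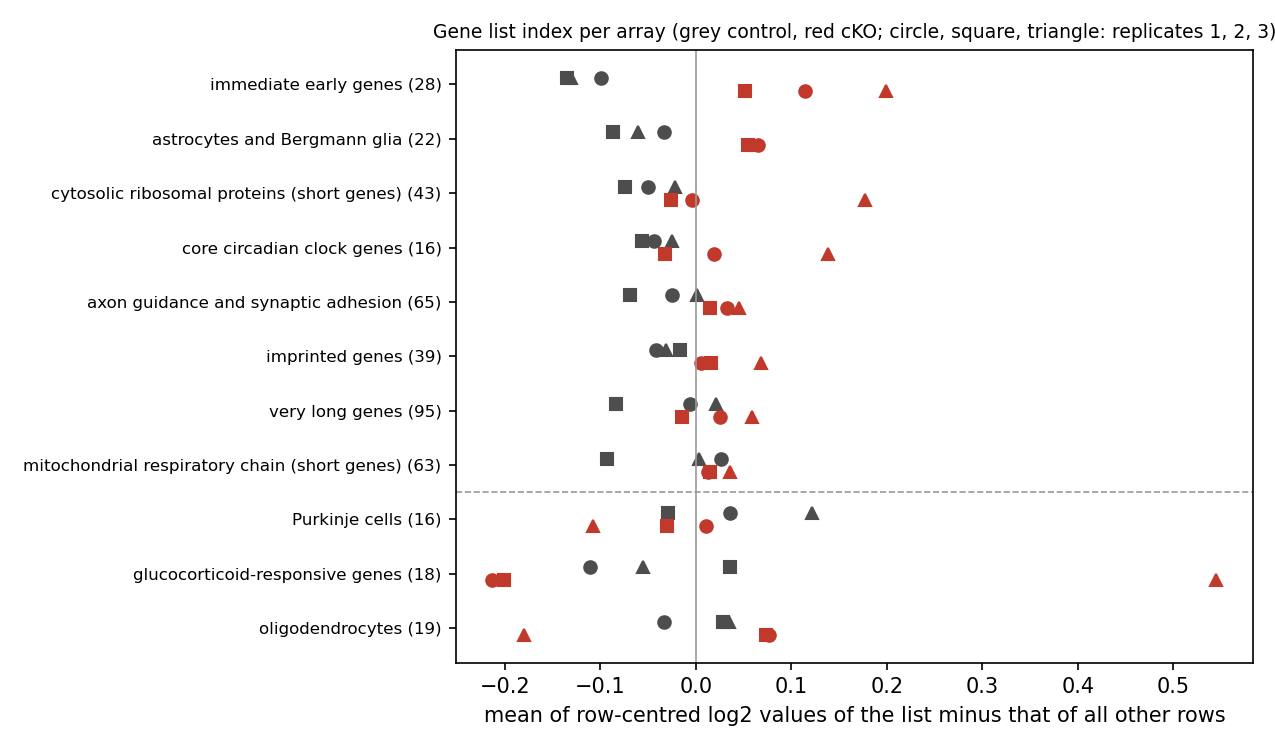
Mean of row-centred log2 values of each gene list minus that of all other rows (horizontal axis) in each control (grey) and cKO (red) array, with circle, square and triangle for replicates 1, 2 and 3 and the number of measured genes in brackets. The 8 lists above the dashed line passed camera and the 3 below did not; cKO replicate 3 lies at 0.545 for glucocorticoid-responsive genes and 0.177 for ribosomal protein genes.

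Of the 37 lists tested, 8 passed camera with the preset correlation, all of them higher in cKO, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05 and the smallest adjusted p was 0.172. The fry test called 0 lists in its directional form and 0 in its mixed form (smallest adjusted p 0.0581). Of the lists chosen for a possible link to DNA methylation, the imprinted genes alone passed with all arrays at the preset correlation, with 21 of 39 members above 0. Germline genes silenced by promoter methylation had a mean of -0.00982 (31 measured, 0 with an unadjusted limma p under 0.05, adjusted p = 0.766), Hox genes -0.0327 (adjusted p = 0.395), clustered protocadherins -0.0507 (adjusted p = 0.0891) and genes earlier studied as targets of the methyl-CpG binding protein MeCP2 0.0463 (adjusted p = 0.134). With arrays left out in turn, the germline mean lay between -0.0187 and 0.00327 and changed sign without control replicate 2 or cKO replicate 3. Without cKO replicate 3 the protocadherins had -0.09 and passed, and without cKO replicate 2 they had -0.0277. Hox genes had -0.0813 and passed without the 2 arrays low in choroid plexus transcripts, and had 0.0235 without control replicate 2 and 0.0174 without cKO replicate 3. The MeCP2 genes had 0.0164 without cKO replicate 3. Among the protocadherins, Pcdhb2 (-0.25) and Pcdhb4 (-0.28) had lower values in every cKO array, and among the MeCP2 genes Mef2c, a neuronal transcription factor, was higher by 0.26 (SE 0.07).

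At the preset correlation and with all arrays and rows as deposited, the neuronal lists gave no call apart from the immediate early and axon guidance genes. Purkinje cell markers had a mean of -0.0854 (adjusted p = 0.0574), with the glutamate transporter Slc1a6 (-0.29) and Pcp2 (-0.11) lower in every cKO array. They passed as lower after quantile normalization, without the 5943 dimmest rows, and without control replicate 2, cKO replicate 1 or cKO replicate 3, and had -0.0457 without control replicate 3. Granule neuron markers (0.0138, adjusted p = 0.595), inhibitory interneurons (0.0415, adjusted p = 0.519) and unipolar brush cells (0.0734, adjusted p = 0.358) did not pass. Without control replicate 2 the granule neuron mean was -0.00394 and the interneuron mean -0.00947, and without control replicate 3 the mean of unipolar brush cells was 0.0284. Glutamate receptors (0.0169, adjusted p = 0.395), GABA and glycine receptors (0.0994, adjusted p = 0.395), sodium and calcium channels (-0.00452, adjusted p = 0.805), potassium channels (0.0132, adjusted p = 0.805) and synaptic vesicle genes (-0.00414, adjusted p = 0.532) did not pass either. Without control replicate 2 the glutamate receptor mean was 0.000178 and the potassium channel mean -0.00034, and without control replicate 3 the sodium and calcium channels had 0.0141 and the vesicle genes 0.0052. The vesicle genes also changed sign without control replicate 1 (0.00758) or cKO replicate 1 (0.00203), and the sodium and calcium channels without cKO replicate 2 (0.00147). The receptor value for GABA and glycine rested on cKO replicate 3 (0.219, against -0.0772 and 0.00737 in cKO replicates 1 and 2). It was 0.0148 without that array, and 0.201, past camera, without the 2 arrays low in choroid plexus transcripts. The median, the mean and the direction of the test did not share a sign in 11 lists, among them glutamate receptors, both ion channel lists, granule neurons, oligodendrocytes and microglia. Members of the channel, receptor and vesicle lists went both ways without passing. Scn8a, a sodium channel (-0.17), Kcnn3, a calcium-activated potassium channel (-0.23), and Bsn, the active zone protein bassoon (-0.18), were lower in every cKO array, and Kcnj16, an inwardly rectifying potassium channel (0.28), Cacna2d1, a calcium channel subunit (0.27), and Grin2b, an NMDA receptor subunit (0.14), were higher in every cKO array. Choroid plexus transcripts differed between arrays of the same group, and the marker Ttr was 8.31 in control replicate 3 and 9.52 in cKO replicate 1 and between 13.29 and 13.47 in the other 4 arrays. Y-linked Eif2s3y was 9.52 and 9.65 in replicate 2 of control and cKO and between 4.97 and 5.04 in the others, so 1 array of each group carried Y-linked signal.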

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

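The sex term, the loss of the choroid-low arrays, the loss of shared list members and 4 gene test settings for Dnmt3a (dim rows, intensity trend, plain test, array weights) were chosen after seeing the data, and the other settings before. Dnmt3a kept its direction in all 15 alternatives, between -0.682 and -0.5542, and passed the threshold only with array weights (-0.6214, adjusted p = 0.0257, range over its alternatives 0.0257 to 0.904). No result of the main comparisons reversed. The single row past the gene test was kept after quantile normalization, centring on medians, the filter on dim rows, the intensity trend, both other thresholds and without cKO replicate 3; the other 5 arrays left out in turn gave 0 calls, so the range was 0 to 1. The calls numbered 0 with the replicate block, 0 with the plain test per row, 0 with the sex term and 0 without the choroid-low arrays (4 arrays, hence fewer samples). Array quality weights gave 57 calls (38 higher, 19 lower, Dnmt3a, Gfap, Fos and Pbx3 among them) and 2395 rows at an unadjusted p under 0.05 against 900; the weights, which did not converge, ran from 0.242 for cKO replicate 3 to 7.08 for control replicate 3, and these calls were not used. The choroid-low setting left 339 such rows.

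The shift of the very long genes lay between 0.0154 (without control replicate 2) and 0.0679 (without control replicate 3) when arrays were left out. It missed the threshold without control replicate 2 (adjusted p = 0.409), with an estimated correlation (0.0459, adjusted p = 0.711), without dim rows (0.031, adjusted p = 0.0506) and without shared members (0.0269, adjusted p = 0.0818, a smaller list). The number of lists past camera lay between 5 (without control replicate 2) and 15 (without cKO replicate 3, 12 up and 3 down, 7 of them among the 8 reported). It was 0 with an estimated correlation, which asks the same question as the preset test, and 0 with directional fry and 0 with mixed fry, which ask others. Beyond the estimated correlation and both fry forms, the ribosomal, immediate early and astrocyte lists lost no call in their other 13 alternatives. These 13 all kept the preset correlation, so they do not test that assumption. The cause of the other changes was not tested.

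The replicate block gave 0 genes and the same 8 lists, with a shift of 0.0459 for the very long genes and -0.60 for Dnmt3a. Deviations from the group means correlated at -0.0404, 0.407 and 0.147 for replicate numbers 1, 2 and 3. These correlations were not tested, so they do not settle whether the numbers pair the samples. The replicate 2 arrays, with the highest correlation, were also the arrays with Y-linked signal. The length thresholds and the correlation with gene length were not run, since gene lengths were not used, and the pseudocount did not apply to log2 values. Signal over background was not known, so dim rows could be limited only by their mean value.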

Other observations

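The list tests of the first paragraph and the comparison of ribosomal protein genes with rows of the same mean value were chosen before their results were seen, and the other tests after. In the camera test as first fixed, the cell types and states not yet described gave no list past the threshold. Cell cycle genes had a mean of 0.0523 relative to other rows (adjusted p = 0.158), with Cdc20 past the test when adjusted over the list alone (0.38). Oligodendrocyte precursors had 0.0414 (adjusted p = 0.402), with the proteoglycan Vcan past the test when adjusted over the list alone (0.33, SE 0.05). MHC and antigen presentation genes had -0.0559 (adjusted p = 0.196), with Cd74 (-0.20) and H2-Ab1 (-0.16) lower in every cKO array. Meninges and fibroblasts (-0.0766, adjusted p = 0.179), blood cells (-0.0232, adjusted p = 0.532), brainstem and midbrain neurons (0.0697, adjusted p = 0.666), choroid plexus (-0.124, adjusted p = 0.805), interferon-responsive genes (0.004, adjusted p = 0.666), cholesterol synthesis (-0.0205, adjusted p = 0.805), heat shock proteins (-0.0142, adjusted p = 0.805), histones (-0.00755, adjusted p = 0.882) and glucocorticoid-responsive genes (0.0875, adjusted p = 0.358) did not pass.

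Several of these values turned on single arrays. Without cKO replicate 3, cell cycle genes (0.0561), oligodendrocyte precursors (0.12), interferon-responsive genes (0.0631) and cholesterol synthesis genes (0.0512) were higher in cKO and passed camera, and glucocorticoid-responsive genes (-0.163) were lower and passed. Glucocorticoid-responsive genes passed as higher without cKO replicate 1 (0.216), without cKO replicate 2 (0.21) and without the choroid-low arrays (0.21), and interferon-responsive genes as lower without cKO replicate 2 (-0.0944). Cell cycle genes also passed after quantile normalization (0.063) and without the 5943 dimmest rows (0.101). Choroid plexus genes passed as lower without control replicate 3 (-0.527) and without the choroid-low arrays (-0.259), and had 0.144 without cKO replicate 1. Heat shock proteins had 0.0518 without cKO replicate 3 and -0.0663 without control replicate 2, and blood cells had 0.0313 without control replicate 2. Histones lay between -0.0347 without control replicate 1 and 0.0204 without control replicate 2. Meninges and fibroblasts had -0.0415 without control replicate 1, and brainstem and midbrain neurons 0.0299 without control replicate 1 and 0.0359 without cKO replicate 3. The median of the brainstem list was -0.0469 with all arrays, and 9 of its 22 members lay above 0. None of the heat shock, blood, histone, meningeal and brainstem values passed.

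cKO replicate 3 differed from the other arrays in several gene groups. It was the highest or lowest array in 61.1% of rows, where 33.3% is expected, and control replicate 2 in 54.3%. It was highest for 17 of 18 glucocorticoid-responsive genes (3 expected), with Pdk4 at 9.57 against 8.30 to 8.95, Sult1a1 at 9.89 and Lcn2 at 9.09, and lowest for 13 of 19 oligodendrocyte genes (3.17 expected). The neuropeptide gene Tac1 was 8.65 in it and at most 6.14 elsewhere, Th was 11.13, Slc17a6 8.85 and Glra1 9.12. Fabp7 (10.75), Tnc (7.22) and Klk6 (8.23) were at their lowest in it. Th and Glra1 were also higher in every cKO array than in every control array, without passing over all rows. Th was 10.08 and 9.76 in cKO replicates 1 and 2 and between 9.02 and 9.51 in controls. Glra1 was 7.98 and 7.82 in cKO replicates 1 and 2 and between 7.40 and 7.67 in controls. The brainstem list as a whole was highest in cKO replicate 3 in 5 of 22 genes (3.67 expected). Of 17 choroid plexus genes, 14 were lowest in control replicate 3 and cKO replicate 1 (1.13 expected).

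Immediate early genes were higher in each cKO array than in each control array. Without cKO replicate 3, 84.1% of the difference in the list's mean was left and both remaining cKO arrays lay above all controls, which argues against that array as the source. In cKO replicates 1 and 2 a shared glucocorticoid response is argued against by the glucocorticoid list. Its mean in these arrays was -0.163 relative to controls, and both lay below every control array. In cKO replicate 3 the glucocorticoid mean (0.545) and the immediate early mean (0.199) were both the highest of the 6 arrays. A glucocorticoid contribution in cKO replicate 3 is therefore not excluded. Time from handling to dissection may also raise immediate early genes and, like the loss of Dnmt3a or the presence of cre, stays open and untested.

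Astrocyte and Bergmann glia markers were higher in cKO, with 99.6% of the difference left without cKO replicate 3. This stability of the mean does not hold for each member. Fabp7, a member, was 12.44 and 12.77 in cKO replicates 1 and 2, 10.75 in cKO replicate 3 and between 11.88 and 12.13 in controls. A lower share of neurons would raise microglial and vascular markers alike, whereas the astrocyte mean minus the mean of those lists was higher by 0.118 (SE 0.023, exact permutation p = 0.1, the smallest possible) and higher in every cKO array than in every control array. Without cKO replicate 3 the microglial (0.0369) and oligodendrocyte (0.0653) lists were higher as well and the vascular list was not (-0.00727, and between -0.0477 and 0.00768 with each array left out in turn). In that setting oligodendrocyte precursors also passed camera as higher and Purkinje cell markers as lower. With all arrays the neuronal marker lists went both ways (Purkinje cells -0.0854, granule neurons 0.0138, inhibitory interneurons 0.0415, unipolar brush cells 0.0734). The contrast with microglial and vascular markers therefore does not exclude a lower share of neurons. A change within astrocytes, such as in Gfap, a change in their number, a lower share of neurons, dissection and genotype may each contribute and stay open.

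Ribosomal protein genes were higher in cKO, but only 34.5% of the difference in their mean was left without cKO replicate 3, so most of it is consistent with a difference of that array. A shift of all bright rows is argued against by 1000 lists of rows with the same mean values, whose mean difference was 0.0041 (the central 95% of the lists ran from -0.0221 to 0.0304) against 0.0881 for the ribosomal genes. Whether genotype adds to the remainder stays open.

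Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. For the gene test, 1 of the 10 splits, the real one, gave as many rows past the threshold (1, highest other 0), and 1 of the 10 splits gave as many at an unadjusted p under 0.001 (56, highest other 9). At an unadjusted p under 0.05 the real split gave 900 rows and the highest other 1288, the split of control replicate 2 with cKO replicates 1 and 2 from the rest. For camera, 8 of the 10 splits called as many lists as the real split (8, highest other 13), and for the very long genes 4 of the 10 splits gave as large a shift (0.0459, highest other 0.0698), so chance was not excluded for the number of lists or for the shift of the very long genes.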
